A study of Mus musculus with 7 samples.

How the data were processed

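RNA from the carotid artery of 7 samples was measured on Affymetrix Mouse 430 2.0 arrays. All offspring carried 1 null allele of Apoe, which encodes apolipoprotein E, a ligand for the clearance of lipoproteins from plasma. In 3 samples the mother was wild type and the father lacked ApoE, and in 4 samples the mother lacked ApoE and the father was wild type. Mice without ApoE are hypercholesterolemic, so the groups differed in which parent had high plasma cholesterol. Groups were taken from the cross given in the labels. Per the labels' protocols, tissue was frozen in liquid nitrogen after dissection, RNA was extracted with a kit for small samples, and an oligo-dT primer and repeated linear amplification were used to make biotin-labelled RNA. The labels give no batch, litter, sex or age, and do not say that each array came from a separate animal. The p-values therefore measure the spread between these samples only.

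The deposited values are MAS5 signals, a linear intensity per probe set, made with GCOS per the submitters' processing notes. The versions are not given in the sources used here. The 2% trimmed mean of every deposited array was 200.0, so each array had been scaled to that target before deposit. The scaling was kept, because a rule set before the data were examined required a change only where trimmed means differed by more than 5%. No detection calls were used here. Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. Symbols were compared with a gene table of assembly GRCm38.p6 and 0 of them changed. No coordinates were used. Probe sets with several symbols or none were tested but not named.

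Signals were transformed to log2(signal + 2), the pseudocount being the 10th percentile of all values rounded to a whole number. The 64 control probe sets were left out of the tests, and probe sets with a mean signal above the 40th percentile (23.6) were kept, which left 27027. Fold changes are on the log2(value + pseudocount) scale, which understates changes of weakly expressed genes. The model was fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, as ApoE-null mother minus wild-type mother, with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. No covariates were used. Intervals are at the 95% level. A gene was represented by its kept probe set with the highest mean signal, which gave 12713 genes. Background was read from 27 probe sets for bacterial transcripts that are not added to the sample. Where all arrays of a group lay at or below the highest of these on the same array, a fold is given as a lower bound, against the mean of those ceilings.

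Before the data were examined, 34 gene lists were fixed for vessel wall cells, for other cells and tissues that a dissected artery can hold, and for pathways of lipid handling, inflammation, matrix, stress, imprinting and chromatin. Of their 479 entries, 435 had a named probe set and 382 were measured. The 30 lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. A list score per array was the mean over genes of the log2 deviation from the mean of the 7 arrays, compared by an exact permutation test on both sides over the 35 splits into groups of 3 and 4. The smallest p that this test can give is 0.0286. List members were also adjusted over their list alone. That adjustment was not in the plan set beforehand, does not correct across lists and was not tried over the splits. A gene that passed only there is described and not called.

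Genes were named by a rule set before the data were examined. It took up to 12 genes per direction past the threshold. It then took the genes with the smallest unadjusted p, an absolute log2 change of at least 1 and no overlap between groups, up to 10 per direction. Genes with predicted or clone names were passed over in that step. In each list past the list test it added the 4 members with the largest moderated statistic in the direction of the list. It also added the 2 members with the smallest p in other lists, Apoe and 3 genes of its locus, Xist, the Y-linked genes and Actb. Gapdh was read from the control probe sets only. Another 9 lists, for thymocytes, thymic epithelium, mature T cells, brown fat, fatty acid oxidation, heart muscle, escape from X inactivation and endoplasmic reticulum chaperones, were written after the data were examined. They are used only in the closing section, apart from the thymocyte score as a covariate for Adcy1.

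The steps were tested on 10 simulated data sets with the real means and spreads. The limma fit called 3.21% of genes changed by 1.5-fold, 28.9% of those changed by 2-fold and 72.7% of those changed by 4-fold, and 42 of 268270 unchanged values. A macrophage list shifted by 1.5-fold was called in 10 of 10 simulations, with 4 calls among 290 unshifted lists. The simulation draws genes independently, so it does not include tissue that differs from array to array. The precision of each value is limited by the number of arrays. Alternatives covered quantile and cyclic loess normalization, the pseudocount, the filter, the variance model, array weights, the choice of probe sets, RNA quality, Y-linked minus Xist signal and tissue scores as covariates, the list test, and leaving out each array in turn.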

Results

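Carotid artery gene expression was compared between heterozygous ApoE offspring of reciprocal crosses, with 3 arrays from offspring of a wild-type mother and 4 from offspring of an ApoE-null mother. The series addressed whether high cholesterol in the mother or the father affects the susceptibility of the offspring to atherosclerosis. All offspring had the same Apoe genotype, so the comparison concerned the parent that lacked ApoE. Both parents differed between the crosses, so an effect of the mother cannot be told apart from one of the father. Median signals were 36.0 to 42.1 per array. Between 61.9% and 74.7% of probe sets per array exceeded the highest of the 27 bacterial probe sets. The ratio of 3 prime to 5 prime Gapdh signal, a measure of RNA integrity after amplification, was 6.06 ± 1.51 (SD, n = 3) with a wild-type mother and 5.78 ± 0.675 (SD, n = 4) with an ApoE-null mother (exact permutation p = 0.8286). The highest ratios for Gapdh (7.80) and Actb (6.71) were on the array of wild-type mother 2. Pearson correlations across probe sets had a mean per array of 0.950 to 0.955 within the wild-type mother group and 0.963 to 0.965 within the ApoE-null mother group. The mean over pairs from different groups was 0.955, and each array of the wild-type mother group correlated more with the other group than with its own. The labels number the arrays of the groups in separate blocks, so any batch that followed this order cannot be told apart from the cross.

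Apoe, the gene with the null allele, was expressed in both groups. Its signal was 3538 ± 449 (SD, n = 3) with a wild-type mother and 2858 ± 282 (SD, n = 4) with an ApoE-null mother, a log2 fold change of -0.30 with a standard error of 0.13 (limma, adjusted p = 0.601). The neighbouring genes of the locus did not pass the test either. Their log2 fold changes were 0.19 for Apoc1, -0.15 for Tomm40 and 0.42 for Bcl3, with intervals that included 0. The value of Apoc1 was -0.49 without wild-type mother 3, and that of Bcl3 -0.02. Xist, the transcript that silences an X chromosome in female cells, had signals of 5174 to 5931 on 6 arrays and 41.2 on the array of wild-type mother 2. The Y-linked genes Eif2s3y, Kdm5d and Uty had a highest signal of 13.6 on that array, below the highest bacterial probe set there (22.0). Actb did not differ, with a log2 fold change of -0.10 that was 0.01 without wild-type mother 2.

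Adcy1, which encodes a calcium-stimulated adenylyl cyclase, was the only gene that passed the test between the crosses. It rose from 110 ± 43.7 (SD, n = 3) with a wild-type mother to 567 ± 88.6 (SD, n = 4) with an ApoE-null mother, a 5.30-fold difference on the log2(value + pseudocount) scale. All 4 arrays of the ApoE-null mother group, at 476.8 to 672.5, lay above the 71.5 to 157.4 of the wild-type mother group. The log2 fold change was 2.41 with a standard error of 0.24 and an interval of 1.87 to 2.94 (limma, adjusted p = 0.0185). No probe set fell at this threshold, while 1161 were higher and 1069 were lower at an unadjusted p under 0.05, against 1351 in all by chance. Adcy1 lost its call in limma when any 1 of the 4 ApoE-null mother arrays was left out (adjusted p = 0.0698 to 0.192), without wild-type mother 2 (adjusted p = 0.0616, with Trav9d-3 as the 1 call), with Y-linked minus Xist signal as covariate (adjusted p = 0.0739) and without an intensity trend (adjusted p = 0.165). It also lost it with the muscle, adipocyte or thymocyte score as covariate (limma, adjusted p = 0.111, 0.103 and 0.9998). Its log2 fold change was 2.14 to 2.70 when single arrays were left out and 0.93 with the thymocyte score, a covariate that nearly repeats the groups (Pearson r = 0.936). The thymocyte list was written after the data were examined.

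**Figure D1:**
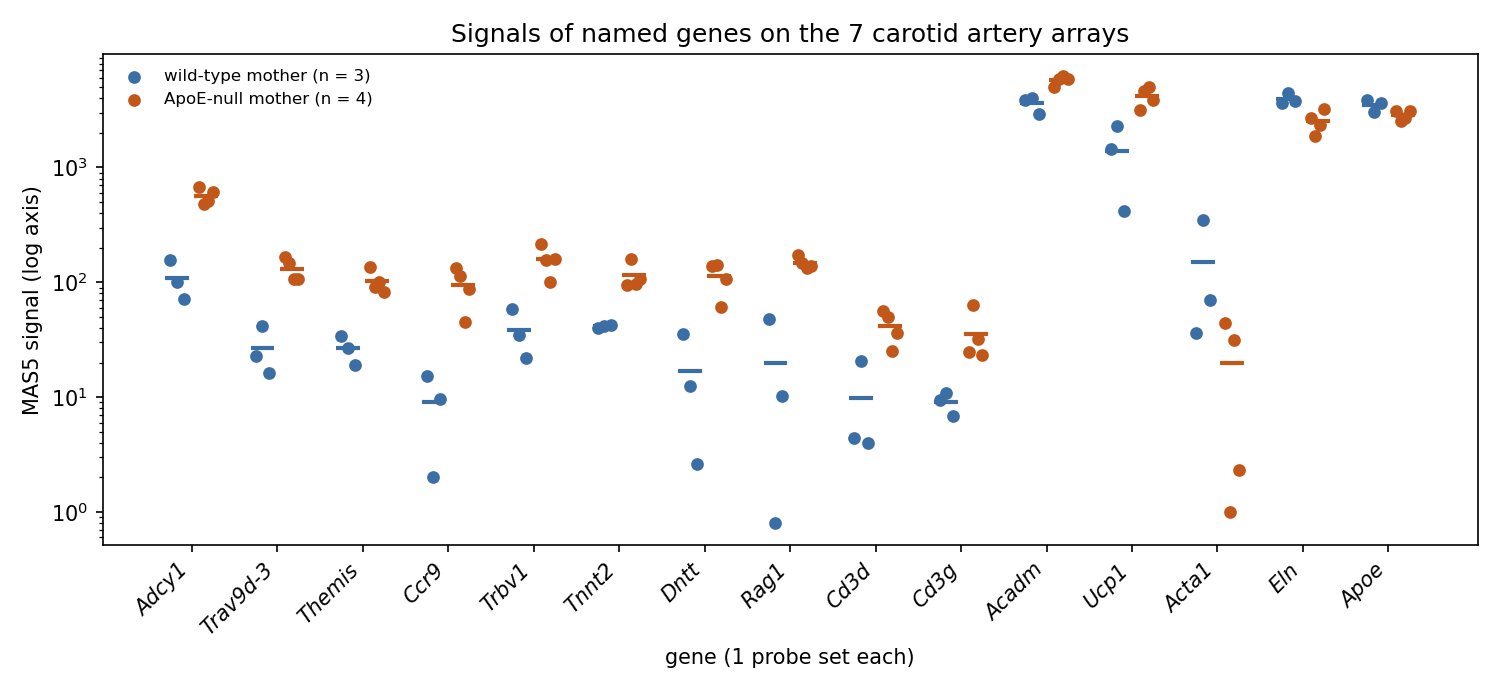
MAS5 signals (log axis) of 15 named genes on the 7 arrays, 1 point per array, with horizontal lines at the group means. The 4 arrays with an ApoE-null mother lie above the 3 with a wild-type mother for Adcy1, while the Acta1 mean of the wild-type mother group is set by 1 array at 348.3.

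Of the 9 genes named for the smallest p among those higher below the threshold, 6 were genes of T cells and their development. Trav9d-3 and Trbv1, which are variable segments of the T cell receptor, had signals of 26.7 ± 13.1 and 38.5 ± 18.7 (SD, n = 3) with a wild-type mother and of 132 ± 30.2 and 159 ± 47.4 (SD, n = 4) with an ApoE-null mother. Themis, needed for thymocyte selection, had a mean of 26.5 against 102. Rag1 and Dntt, which act in the recombination of antigen receptor genes, had means of 19.8 against 148 and 16.8 against 112, and the chemokine receptor gene Ccr9 had a mean of 9 against 94.5. Log2 fold changes of these 6 genes were 1.88 to 3.64, and none passed the test (limma, adjusted p = 0.0901 to 0.317). With a wild-type mother, Ccr9 and Dntt were at the level of the bacterial probe sets on 2 of 3 arrays and Rag1 on 1 of 3, so their fold changes rest partly on background. Without wild-type mother 1, on which Rag1 was 48.3 against 0.8 and 10.3 on the other arrays of its group, Rag1, Dntt, Ccr9, Themis and Trbv1 passed (limma, adjusted p = 0.0117 to 0.0408), and 16 probe sets were called higher and 2 lower. Probe sets marked as open to cross-hybridisation represent Trav9d-3, Trbv1, Ccr9 and Dntt.

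The list of T and B lymphocyte markers was higher with an ApoE-null mother, with 5 of 6 measured genes positive and a median log2 fold change of 0.67 (camera of limma, adjusted p = 0.00491, and adjusted p = 0.878 with an estimated correlation). None of its genes passed over all probe sets, and 3 passed when adjusted over the list alone, which does not correct across lists. The T cell receptor subunit genes Cd3d and Cd3g were at the level of the bacterial probe sets on every array of the wild-type mother group, and were at least 2.74-fold and 2.28-fold higher with an ApoE-null mother. Ptprc, a gene of all leukocytes, had a log2 fold change of 0.79, and the B cell gene Ms4a1 of 0.55. The list score was -0.49 ± 0.28 (SD, n = 3) against 0.37 ± 0.33 (SD, n = 4; exact permutation p = 0.0571). The erythrocyte genes Alas2 and Slc4a1, 2 of 7 list genes and too few for the list test, had log2 fold changes of 1.24 and 0.72. Both passed when adjusted over their list alone, which here covers 2 genes. Their score overlapped between groups, at -0.85 to -0.10 with a wild-type mother and -0.19 to 0.85 with an ApoE-null mother. Tnnt2 (1.40), Zfp991 (1.33) and Angpt2 (1.18) completed the genes named for the smallest p among those higher on the log2 scale, without passing (limma, adjusted p = 0.120 to 0.367).

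Among the genes with lower signals in the ApoE-null mother group, none passed the test. Genes were represented by their strongest probe set, and predicted or clone names were passed over. Among those with an absolute log2 change of at least 1 and no overlap between groups, the smallest p belonged to Haus8, a subunit of a spindle complex, with 211 ± 61.8 (SD, n = 3) against 89.3 ± 11.0 (SD, n = 4), and Ndufa4l2, a mitochondrial gene induced by hypoxia, with 191 ± 82.4 (SD, n = 3) against 69.8 ± 10.4 (SD, n = 4). Ddx55, Itgb4, Cc2d1b, Arnt2, Ifit1bl2, Tmem198, Cadm1 and Tepsin followed, with log2 fold changes of -1.04 to -1.52. Tepsin, Ifit1bl2 and Cc2d1b were at the level of the bacterial probe sets on 3, 2 and 1 of 4 ApoE-null mother arrays, so their fold changes rest partly on background. Adjusted p-values of these 10 genes were 0.278 to 0.477 in limma. Groups did not overlap for 2168 probe sets, or 8.02%, where chance gives 5.71%.

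Genes of lipid uptake and fatty acid use were higher with an ApoE-null mother, with 13 of 15 measured genes positive and a median log2 fold change of 0.28 (camera of limma, adjusted p = 0.00234, and adjusted p = 0.878 with an estimated correlation). Acadm, a dehydrogenase of fatty acid oxidation, had signals of 3612 ± 603 (SD, n = 3) and 5778 ± 496 (SD, n = 4), and was the 1 gene that passed when adjusted over the list alone. Vldlr, Cd36 and Lpl, which act in lipoprotein and fatty acid uptake, had log2 fold changes of 0.46, 0.81 and 0.42. Without wild-type mother 3 those of Cd36 and Lpl were 0.35 and 0.19, and without wild-type mother 2 that of Lpl was 0.64. The list of white and brown adipocyte genes was also higher, with 11 of 13 genes positive and a median of 0.13 (camera of limma, adjusted p = 0.0229, and adjusted p = 0.919 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, had signals of 1388 ± 940 (SD, n = 3) and 4177 ± 840 (SD, n = 4), and was the 1 adipocyte gene that passed when adjusted over the list alone. Its log2 fold change was 1.88, and 1.17 without wild-type mother 3. Elovl3, Cox7a1 and Pck1 had log2 fold changes of 1.45, 1.10 and 0.75. The value of Cox7a1 was 0.34 without wild-type mother 3 and 1.80 without wild-type mother 2, and that of Pck1 was 0.45 without wild-type mother 2 or ApoE-null mother 3. The array of wild-type mother 3 had the lowest scores, -0.68 for the lipid list and -0.99 for the adipocyte list, and without it both calls were lost (camera of limma, adjusted p = 0.695 and 0.828). The adipocyte call was also lost without ApoE-null mother 3 or ApoE-null mother 4 (adjusted p = 0.0571 and 0.2501 in camera of limma). Scores overlapped between groups. Wild-type mother 2 was at 0.22 for the lipid list and 0.28 for the adipocyte list. The ApoE-null mother arrays were at 0.02 to 0.22 and -0.18 to 0.44 (exact permutation p = 0.171 and 0.286).

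Skeletal muscle genes were lower with an ApoE-null mother, with 10 of 11 measured genes negative and a median log2 fold change of -1.50 (camera of limma, adjusted p = 0.00234, and adjusted p = 0.878 with an estimated correlation). None passed when adjusted over the list alone. The difference lay mostly in the array of wild-type mother 2, with a list score of 3.02 where the other arrays had scores of -0.90 to 0.06. Acta1, the actin of skeletal muscle, had a signal of 348.3 on that array and 1.0 to 69.4 on the others, and Tnnc2 525.8 against 7.9 to 23.4. Tnnt3 and Pvalb had signals of 229.5 and 385.3 on that array. Without it the call was lost (camera of limma, adjusted p = 0.4996). Tnnt3, Pvalb and Tnnc2 were then at log2 fold changes of -0.53, -0.39 and -0.49. Acta1 stayed negative, at -3.74 to -2.14 when each array was left out, against -3.06 with all arrays. However, Acta1 and Tnnc2 were at the level of the bacterial probe sets on 2 of 4 ApoE-null mother arrays. Without wild-type mother 2 the groups overlapped for Acta1, at 36.3 and 69.4 against 1.0 to 43.8, so its value rests partly on background. The array of wild-type mother 2 also had a Xist signal of only 41.2 and the highest 3 prime to 5 prime ratios.

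Schwann cell and nerve genes were lower with an ApoE-null mother in 8 of 8 measured genes, with a median log2 fold change of -0.29 (camera of limma, adjusted p = 0.0330, and adjusted p = 0.878 with an estimated correlation). Cnp, a myelin enzyme, had signals of 1299 ± 659 (SD, n = 3) and 601 ± 174 (SD, n = 4), and was the 1 gene that passed when adjusted over the list alone. Its log2 fold change was -1.04, and -0.66 without wild-type mother 3, where its signal was 2060.5. Sox10, Mbp and Pmp22 had log2 fold changes of -2.05, -1.22 and -0.16. When each array was left out, Mbp was at -1.92 to -0.58 and Pmp22 at -0.23 to -0.09. Sox10 was at the level of the bacterial probe sets on 2 of 4 ApoE-null mother arrays. Scores overlapped, at -0.29 to 0.79 with a wild-type mother and -1.09 to 0.45 with an ApoE-null mother, and the call was lost in camera of limma without wild-type mother 1 (adjusted p = 0.132), wild-type mother 3 (adjusted p = 0.194), ApoE-null mother 2 (adjusted p = 0.0535) or ApoE-null mother 4 (adjusted p = 0.2501). Genes of ganglion and glomus cells, the sensory cells of the carotid body, were lower in 11 of 11 measured genes with a median of -0.78 (camera of limma, adjusted p = 0.0377, and adjusted p = 0.919 with an estimated correlation). None passed when adjusted over the list alone. Uchl1, Chga, Gap43 and Scg2 had log2 fold changes of -0.78, -1.51, -1.34 and -0.74. Without wild-type mother 1 they were -0.39, -0.87, -0.42 and 0.06. Without wild-type mother 3 Gap43 and Scg2 were at -2.29 and -1.80, and Chga, at -2.70, was called lower (limma, adjusted p = 0.0308). Chga was at -0.98 and Scg2 at -0.47 without wild-type mother 2, and Scg2 at -0.48 without ApoE-null mother 1. The score of wild-type mother 1 was 2.51, with a signal of 687.5 for Th, the first enzyme of catecholamine synthesis, and without that array the list turned to higher (camera of limma, adjusted p = 0.890). The call was also lost in camera of limma without wild-type mother 2 (adjusted p = 0.0930), ApoE-null mother 1 (adjusted p = 0.191) or ApoE-null mother 4 (adjusted p = 0.284). With an estimated correlation 0 of the 6 lists called by camera held, and fry called 0 lists for a shared direction. Of the list scores, 0 passed the exact permutation test (smallest p = 0.0571). At the preset correlation, 31 of the 35 splits of the arrays called at least 6 lists. Camera calls here and in the lists below carry that limit.

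**Figure D2:**
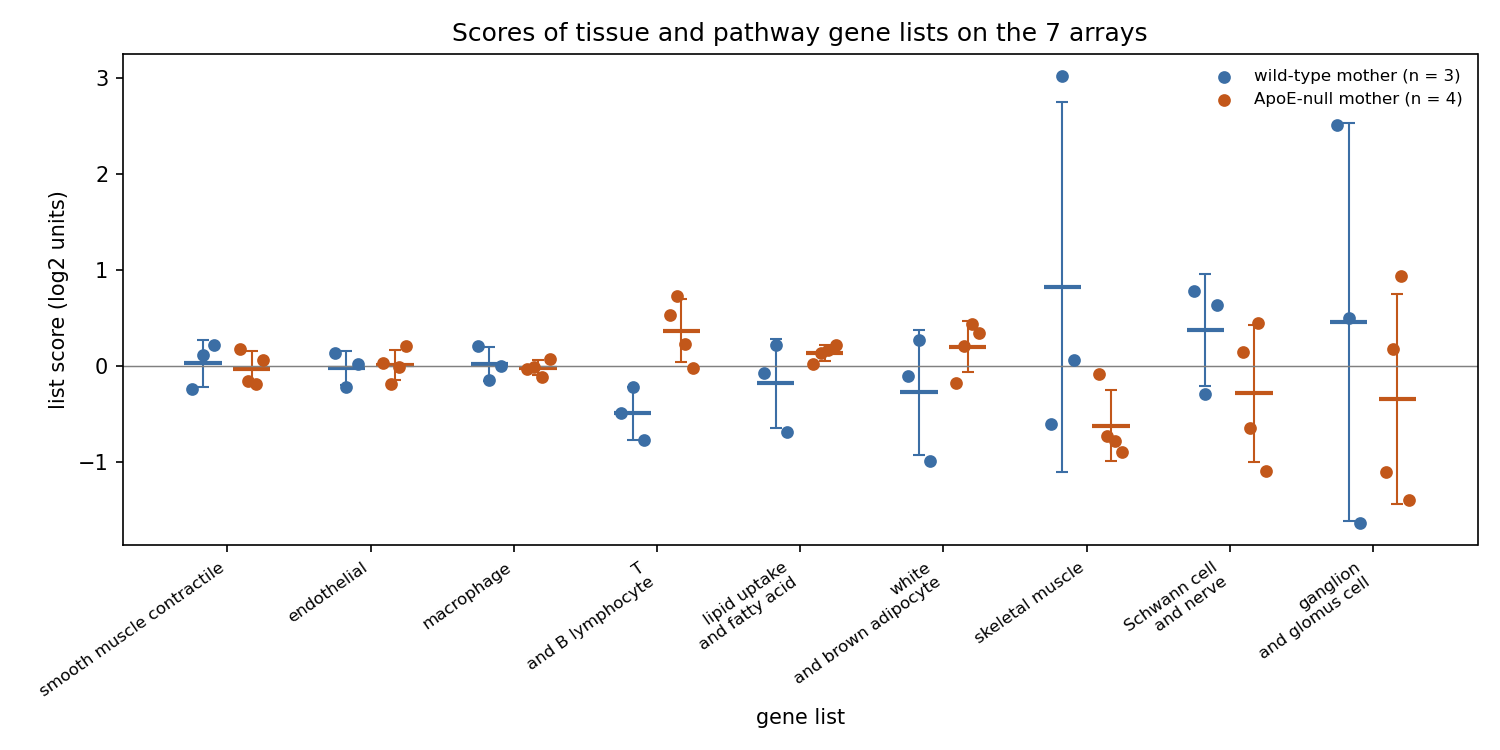
Scores of 9 gene lists (log2 units, mean deviation from the 7 arrays) with 1 point per array, horizontal lines at group means and bars of 1 SD. Single arrays set the high skeletal muscle score (3.02) and ganglion score (2.51) of the wild-type mother group, and scores of smooth muscle, endothelial and macrophage lists overlap between groups.

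Markers of the vessel wall itself did not pass the list test. The contractile smooth muscle list had a median log2 fold change of -0.07 over 16 genes and the endothelial list of 0.03 over 13 genes (camera of limma, adjusted p = 0.693 and 0.974). Actg2 and Mylk, genes of smooth muscle contraction, had log2 fold changes of -0.34 and 0.21, and the endothelial receptor genes Tek and Eng of 0.49 and -0.35. The smooth muscle list was called lower in camera of limma without wild-type mother 1 (adjusted p = 0.00937). Genes of the extracellular matrix had a median of -0.05 over 15 genes (camera of limma, adjusted p = 0.5848). Eln, which encodes elastin, had signals of 3988 ± 443 (SD, n = 3) and 2546 ± 554 (SD, n = 4), without overlap, and was the 1 matrix gene that passed when adjusted over the list alone; it did not pass over all probe sets (limma, adjusted p = 0.459). Tnc had a log2 fold change of 0.54. The metalloproteinase list had a median of -0.02, a mean of 0.06 and a test direction of higher, with Mmp3 at 0.69 and Mmp14 at -0.30 (camera of limma, adjusted p = 0.948).

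Vasoactive genes went both ways. Of 12 measured genes, Ece1, the enzyme that activates endothelin, had signals of 1067 ± 113 (SD, n = 3) and 690 ± 59.96 (SD, n = 4), and Gucy1a1, a subunit of the nitric oxide receptor, had 1544 ± 105 (SD, n = 3) and 2024 ± 30.8 (SD, n = 4). Both passed when adjusted over the list alone and neither over all probe sets (limma, adjusted p = 0.415 and 0.485). The list had a median of 0.19 and no shared direction (camera of limma, adjusted p = 0.750), but fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.0113 in limma. The other list called by that mixed test was that of T and B lymphocytes (fry of limma, adjusted p = 0.0413). In the TGF-beta and BMP list the median was 0.01, the mean -0.12 and the test direction lower, with the inhibitory genes Smad7 and Smad6 at -0.56 and -0.57 (camera of limma, adjusted p = 0.559).

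Inflammatory groups did not pass. The macrophage list had a median of 0.03, a mean of -0.04 and a test direction of lower over 15 genes, with Cd74 at -0.87 and C1qb at 0.36 on the log2 scale (camera of limma, adjusted p = 0.938). Chemokine, cytokine and adhesion genes had a median of 0.05, a mean of -0.04 and a test direction of higher, with Cxcl1 at -0.72 and Cxcl10 at -0.64 (camera of limma, adjusted p = 0.948). Cxcl10 was at -0.07 without ApoE-null mother 2, -0.98 without ApoE-null mother 4 and -0.41 without wild-type mother 3, and Cxcl1 at -0.47 without ApoE-null mother 3. Of 10 interferon-stimulated genes, 8 were negative, and Rsad2 (0.86) and Ifit1 (-0.89) were opposite; 1 gene higher and 1 lower passed when adjusted over the list alone (camera of limma, adjusted p = 0.0891). That list was called lower in camera of limma without wild-type mother 2 (adjusted p = 0.00316), without ApoE-null mother 1 (adjusted p = 0.0301) and with the skeletal muscle score as covariate (adjusted p = 0.0207). Complement and coagulation genes had a median of 0.12, with Plat and F3 at 0.23 and 0.24 (camera of limma, adjusted p = 0.284). Mast cell genes had a median of 0.21, with Mcpt4 at 0.42 and Kit at 0.27, values that were -0.11 and -0.11 without wild-type mother 3 (camera of limma, adjusted p = 0.693).

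Genes of cholesterol synthesis and efflux did not pass as groups. The synthesis list had a median log2 fold change of -0.11 over 14 genes (camera of limma, adjusted p = 0.938), with Cyp51 at 0.79, the 1 gene of the list that passed when adjusted over the list alone, and Hmgcs1 at 0.35. Targets of the sterol receptor LXR had a median of -0.04 over 12 genes, with Abcg1, a cholesterol exporter, at 0.30 (camera of limma, adjusted p = 0.938). Oxidative phosphorylation genes were positive in 13 of 16 cases with a median of 0.07, and Atp5b and Uqcrc2 were at 0.43 and 0.51 (camera of limma, adjusted p = 0.0853). That list was called higher in camera of limma without wild-type mother 2 (adjusted p = 1.58e-09), under quantile normalization (adjusted p = 0.0237) and with the skeletal muscle score as covariate (adjusted p = 4.78e-09). These calls used the preset correlation. In the reported setting the oxidative phosphorylation list had an adjusted p of 0.962 with an estimated correlation in camera of limma. Fry of limma gave an adjusted p of 0.893, and the list score an exact permutation p of 0.457. Antioxidant genes had a median of 0.02, with Cat at 0.32 and Gpx3 at 0.39 (camera of limma, adjusted p = 0.5848).

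Imprinted genes, of which the allele from 1 parent is expressed, did not pass as groups. Paternally expressed genes had a median of -0.01, a mean of 0.05 and a test direction of higher, and maternally expressed genes a median of -0.02 and a mean of -0.09 on the log2 scale (camera of limma, adjusted p = 0.693 for both). Plagl1, at 0.71, passed when adjusted over the paternal list alone, and Mest was at -0.27, or 0.07 without wild-type mother 1. Meg3 and Slc22a18 were at -0.47 and -0.78. Histone lysine methyltransferases and demethylases had a median of -0.004, a mean of 0.004 and a test direction of lower over 19 genes, with Smyd2 at -0.33 and Kdm4a at 0.38, and the DNA methylation list had a median of -0.16, with Mbd3 at -0.69 and Mbd1 at -0.59 (camera of limma, adjusted p = 0.938 and 0.173).

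Heat shock and unfolded protein genes had a median of -0.12 over 14 genes, with the chaperone genes Hsph1 and Hspa8 at -0.63 and -0.49 (camera of limma, adjusted p = 0.0773). That list was called lower in camera of limma without ApoE-null mother 2 (adjusted p = 0.00304), without ApoE-null mother 3 (adjusted p = 0.0348), under quantile normalization (adjusted p = 0.0486) and with the skeletal muscle score as covariate (adjusted p = 0.0498). Immediate early genes had a median of -0.07, with Nr4a1 at 0.60 and Zfp36 at -0.39 (camera of limma, adjusted p = 0.559). Clock genes had a median of -0.21, with Nr1d1 at -0.59 and Clock at -0.27 (camera of limma, adjusted p = 0.227), and were called lower without wild-type mother 2, without ApoE-null mother 2 and with the skeletal muscle score as covariate (camera of limma, adjusted p = 0.0297, 0.0211 and 0.0191). Cell cycle genes had a median of 0.11, with Ccnd1 at -0.52 and Pcna at 0.41 (camera of limma, adjusted p = 0.938). Steroid response genes had a median of 0.19, with Nr3c2 at 0.45 and Esr1 at 0.30 (camera of limma, adjusted p = 0.173), and were called higher without wild-type mother 3 and with the adipocyte score as covariate (camera of limma, adjusted p = 0.00547 and 0.00708). The thyroid and parathyroid list had 1 measured gene, at -0.34, too few for the list test.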

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

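The tests of thymus tissue, mature T cells, vessel wall share, fat tissue, a male animal, a single X chromosome and both X chromosomes active were chosen after the results were seen. The tests of other splits were set before. The test of RNA quality was recorded as set before, but the fatty acid oxidation list it uses was written after the data were examined.

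Of 130 measures tested in the ApoE-null mother group, 4 had 1 array far from the other 3, where chance gives about 6.5. Zfp991 was 202.3 on ApoE-null mother 3 and 97.2 to 112.8 on the others. Gap43 was 107.1 on ApoE-null mother 3 and 21.6 to 29.4 on the others. Plagl1 was 688.7 on ApoE-null mother 4 and 920.8 to 957.8 on the others. Nr3c2 was 258.2 on ApoE-null mother 1 and 174.7 to 186.5 on the others.

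Thymocyte genes were higher with an ApoE-null mother, but the lists for them were written after 6 of their genes (Rag1, Dntt, Themis, Ccr9, Cd3d and Cd3g) had been seen, so their values restate the pattern. Thymus tissue in the samples stays open: 92.9% of 14 immature thymocyte genes were positive (score difference 1.82, exact permutation p = 0.0286, the smallest the test can give), and thymic epithelium genes, near background, differed by 0.10 (exact permutation p = 0.686). Mature T cells in the wall stay open too: the score of Rag1, Rag2, Dntt and Ptcra, which they do not express, was higher by 2.08 (exact permutation p = 0.0286), but Rag2 and Ptcra were below the intensity filter, and mature T cell genes were positive in 5 of 6 cases with a score higher by 0.40 (exact permutation p = 0.0571). A lower share of vessel wall cells, which would raise all other tissues alike, gains no support from the wall markers but stays open. Smooth muscle contractile and endothelial scores differed by -0.06 and 0.03 (exact permutation p = 0.771 and 0.714). Scores of skeletal muscle, Schwann cell, ganglion and macrophage lists differed by -1.45, -0.66, -0.80 and -0.04, and those of adipocyte and mast cell lists by 0.48 and 0.17. None had an exact permutation p under 0.05, and single arrays set the muscle and ganglion scores. The thymocyte score minus the mean score of 6 lists for other tissues was higher by 2.31 (exact permutation p = 0.0286), but it holds genes picked for the pattern. With the T and B lymphocyte list, or the other 5 measured thymocyte genes, that difference was 1.25 or 1.505 (exact permutation p = 0.0571 for both). Neither set is independent of the pattern. The first holds Cd3d and Cd3g, and the second comes from the list written after the data were examined. If 1 tissue supplies these genes they amount to 1 observation, and whether it came with dissection or from a difference due to the cross was not tested.

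Fatty acid oxidation genes, in a list written after the data were seen, were positive in 23 of 25 cases, with a score higher by 0.524 with an ApoE-null mother (exact permutation p = 0.0571) and by 0.347 without wild-type mother 3. More fat tissue cannot be told apart from a change within it: the oxidation score minus that of brown adipocyte identity, itself higher by 0.33 (exact permutation p = 0.200), differed by 0.195 (exact permutation p = 0.229). The ratio of Ucp1 to the brown fat gene Cidea was 0.578 ± 0.037 (SD, n = 3) with a wild-type mother and 1.375 ± 0.083 (SD, n = 4) with an ApoE-null mother (exact permutation p = 0.0286). Ucp1 had been singled out by its value, so the ratio does not decide for the oxidation genes. Log2 fold changes were 0.10 for Adipoq, -0.08 for Ebf2 and 0.23 for Prdm16, but 0.63 for Cidea and 1.10 for Cox7a1. With the Gapdh ratio as covariate for RNA quality the difference in the oxidation score was 0.527, with a lower bound of -0.106. That difference did not shrink, which gives RNA quality no support and does not exclude it. An effect of the cross on brown fat, through the mother or the father, stays open and untested.

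The array of wild-type mother 2 had little Xist signal: 41.2 on the strongest probe set, above the bacterial ceiling of 22.0, and 7.7 and 6.7 on the others, below it. A male animal is argued against by the highest Y-linked signal of 13.6, below the bacterial ceiling of 22.0, and loss of silencing with both X chromosomes active by 404 X-linked genes, whose median relative to autosomal genes was -0.038. A single X chromosome may account for the pattern: 5 genes that escape X inactivation had a median log2 difference of -0.28 from the other arrays, with Kdm6a (-1.49), Eif2s3x (-0.61) and Kdm5c (-0.28) lowest there. Of the 17 kept probe sets of these genes and of Ddx3x and Pbdc1, 12 were lowest on that array and at most 2 on any other. Probe sets of 1 gene are not separate cases, and the share of all kept probe sets lowest there was not counted. That array also had the fewest probe sets above the bacterial ceiling (61.9%) and the highest 3 prime to 5 prime ratios, so RNA quality was not excluded. Probe sets of Ddx3x disagreed: 57.4 against 169.0 to 286.4 and 2172.5 against 2734.5 to 3727.6, but 5265.6 against 4733.7 to 5777.5 for the strongest. Of all 12713 genes, 0.802% were lower than Kdm6a, 7.36% lower than Eif2s3x and 23.3% lower than Kdm5c on that array.

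Chance cannot be excluded for any of the 3 counts tested over the splits. Of the 35 splits of the 7 arrays, 4 gave at least the 1 called probe set of the real split, and the highest other split gave 13. For unadjusted p, 5 splits gave at least the real 2230 probe sets, with 3042 as the highest other. At least the 6 gene lists of the real split were called in 31 of 35 splits, with 11 as the highest other, so a count of list calls at the preset correlation carries no evidence for the cross. The 1 split with 13 called probe sets set wild-type mother 2 with ApoE-null mother 2 and 4 against the rest, and why it gave more was not tested.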

How the results depend on the processing

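The covariates for thymocytes (genes) and for muscle and adipocytes (lists) were chosen after the data were examined, as was singling out wild-type mother 2. No paired analysis was possible because the labels give no replicate numbers shared between the groups. The covariate of Y-linked minus Xist signal varies mostly through wild-type mother 2. Of 2179 alternative values of named genes, 2129 kept their direction and side of the threshold, 31 turned, 10 lost and 9 gained a call. Of 507 for lists, 402 were kept, 59 turned, 30 lost and 16 gained a call. The cause was not tested unless stated.

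Adcy1 was called by limma in 13 of 23 alternatives, with a log2 fold change of 0.93 to 2.70 and an adjusted p of 0.00186 to 0.9998. The count of probe sets called higher, 1 in the reported setting, was 2 under quantile normalization, array weights and the Gapdh ratio as covariate, and 0 without an intensity trend and with the muscle, adipocyte or thymocyte score or Y-linked minus Xist signal as covariate. Leaving out each array gave 0 to 16 called higher and 0 to 2 called lower. Without wild-type mother 1 it gave 16 and 2, without wild-type mother 3 it gave 3 and 1, without any 1 of the 4 ApoE-null mother arrays it gave 0, and without wild-type mother 2 the 1 call was Trav9d-3 (adjusted p = 0.04996) and not Adcy1 (adjusted p = 0.0616). At unadjusted p, 1 probe set per gene gave 564 higher and 548 lower, since fewer were tested, and the thymocyte covariate gave 180 and 394. That covariate nearly repeats the groups (Pearson r = 0.936 over the 7 arrays), so its fit separates little. Leaving out each array gave 726 to 1478 higher, the lowest 726 without ApoE-null mother 3 and 762 without ApoE-null mother 2. Lists called lower, 3 in the reported setting, were 0 with the filter at the 60th percentile, 5 with the muscle covariate and 1 to 4 when arrays were left out, with 1 without ApoE-null mother 4. With an estimated correlation 0 lists were higher and 0 lower, and with fry also 0 and 0. Under quantile normalization 1 list score reached the smallest exact p.

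Values in brackets are log2 fold changes. With Y-linked minus Xist signal as covariate, the direction turned for Actb (0.00384). With the skeletal muscle score as covariate, the direction turned for Actb (0.0672). With the adipocyte score as covariate, the direction turned for Mcpt4 (-0.13), Kit (-0.18) and Apoc1 (-0.79). With the thymocyte score as covariate, the direction turned for Trbv1 (-0.33), Dntt (-1.42), Rag1 (-0.29), Actg2 (0.0959), Ptprc (-0.78), Cxcl10 (0.99), Tnnt3 (0.51), Tnnc2 (1.09), Mcpt4 (-0.96), Kit (-0.68), Nr1d1 (0.0857), Clock (0.16), Plagl1 (-2.50e-04), Esr1 (-0.00102), Smad6 (0.45), F3 (-0.0618), Tomm40 (0.50), Bcl3 (-0.63) and Actb (0.30). Of 96 named genes, 35 had a value that turned or moved by over 1.5 times without some array. When each array was left out, values ranged over Scg2 -1.80 to 0.0639, Mcpt4 -0.11 to 0.78, Kit -0.11 to 0.63, Mest -0.51 to 0.0708, Apoc1 -0.49 to 0.92, Bcl3 -0.0209 to 0.82 and Actb -0.23 to 0.0130.

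Of the called lists, Schwann cell and nerve lost its call without a filter (adjusted p = 0.0664), with the filter at the 60th percentile (adjusted p = 0.0652), with the mean over probe sets (adjusted p = 0.0552) and with the adipocyte covariate (adjusted p = 0.303) in camera of limma. The ganglion list lost it with the filter at the 60th percentile (adjusted p = 0.0652) and the lipid list with the adipocyte covariate (adjusted p = 0.786) in camera of limma.

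For lists, values are adjusted p from the list test, and except for skeletal muscle, adipocyte and ganglion genes the lists named here were not called in the reported setting. A list's own score as covariate removes it by construction. Without a filter, the direction turned for endothelial (0.923), cell cycle (0.923), paternally expressed (0.866) and vasoactive (0.964). With a filter at the 60th percentile, the direction turned for endothelial (0.987), chemokine (0.987), metalloproteinase (0.987), cholesterol biosynthesis (0.987) and cell cycle (0.987). With the skeletal muscle score as covariate, the direction turned for smooth muscle contractile (0.255), matrix (0.258), endothelial (0.343), cholesterol biosynthesis (0.146), LXR target (0.802), skeletal muscle (0.910), cell cycle (0.910) and complement and coagulation (0.615). With the adipocyte score as covariate, the direction turned for smooth muscle contractile (0.726), macrophage (0.983), white and brown adipocyte (0.786), mast cell (0.303), oxidative phosphorylation (0.607), histone methylation (0.774) and paternally expressed (0.983). On ranks, the direction turned for endothelial (0.985) and metalloproteinase (0.985). With the mean over probe sets, the direction turned for chemokine (0.996) and histone methylation (0.996). When each array was left out, lists that turned at least once had adjusted p of smooth muscle contractile 0.00937 to 0.970, matrix 0.110 to 0.942, endothelial 0.496 to 0.997, macrophage 0.340 to 0.997, chemokine 0.647 to 0.970, metalloproteinase 0.824 to 0.983, cholesterol biosynthesis 0.0541 to 0.970, LXR target 0.705 to 0.974, ganglion and glomus 2.36e-10 to 0.890, mast cell 0.188 to 0.970, oxidative phosphorylation 1.58e-09 to 0.904, cell cycle 0.635 to 0.970, histone methylation 0.406 to 0.983, paternally expressed 0.262 to 0.942, maternally expressed 0.190 to 0.970 and complement and coagulation 0.115 to 0.967.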

Other observations

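The tests in this part were chosen after the data were examined, and its genes were singled out by their values. Chaperone genes of the endoplasmic reticulum had lower signals with an ApoE-null mother in 10 of 15 cases. Manf was 1954 ± 220 (SD, n = 3) and 1174 ± 308 (SD, n = 4), and Creld2 was 567 ± 55.9 (SD, n = 3) and 360 ± 61.3 (SD, n = 4), both without overlap. Hsp90b1 and Pdia3 had positive log2 fold changes of 0.15 and 0.44. The list score differed by -0.17 (exact permutation p = 0.229), and neither Manf nor Creld2 passed (limma, adjusted p = 0.458 and 0.459). At the preset correlation the list was called lower (camera of limma, adjusted p = 0.0188), but it was written after the data were examined.

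The noncoding genes Meg3, Rian and Airn were singled out by their values, none of their probe sets passed, and probe sets of 1 transcript are not separate cases. For Meg3, expressed from the maternal allele, the log2 fold changes were -0.09 to -1.15, with 431 ± 42.6 (SD, n = 3) and 194 ± 19.8 (SD, n = 4) on the probe set at -1.15 (limma, adjusted p = 0.0901) and -0.47 on the most strongly expressed one. For Airn, expressed from the paternal allele, they were -0.48 to -0.90, the strongest at 202 ± 24.4 (SD, n = 3) and 108 ± 19.95 (SD, n = 4) without passing (limma, adjusted p = 0.383), and for Rian -0.24 to -0.74. For Cd8a, 4 of 5 probe sets were higher without overlap, but at background on 1 to 3 of the 3 arrays with a wild-type mother, and the probe set with the highest signal, which is open to cross-hybridisation, had a log2 fold change of -0.15 (limma, adjusted p = 0.904).

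Heart muscle genes were divided. Tnnt2 had signals of 41.2 ± 1.31 (SD, n = 3) and 115 ± 31.0 (SD, n = 4), and Tbx5, at background on 2 of 3 arrays with a wild-type mother, had means of 10.3 and 38.8, whereas Actc1 had a log2 fold change of -0.95. The heart muscle score differed by 0.44, but only 3 of 7 genes passed the intensity filter and the list was written after Tnnt2 was seen, so it does not describe heart muscle genes. Genes that escape X inactivation had a score difference of 0.20 (exact permutation p = 0.143). It includes the low values of wild-type mother 2 described above, and the SD was 0.264 with a wild-type mother and 0.069 with an ApoE-null mother.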
